A study of Arabidopsis thaliana with 3 samples.

How the data were processed

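The series holds 3 samples of 1 kind, stigmatic papilla cells of the Arabidopsis accession C24, and its design text speaks of 3 independent experiments. Per the labels' protocols, stage 12 buds were fixed in an acetic acid and ethanol mixture and embedded, and papilla cells were cut out by laser microdissection. RNA was then isolated with a kit for small samples, mixed with a spike mix, amplified and labelled with Cy3. Amplification of small samples and fixation can distort levels, and probes designed on the reference accession can bind C24 transcripts less well where the sequences differ.

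Each sample has 1 scanner output file from a 1-colour Agilent array. The deposited values used here were each spot's processed intensity on a linear scale, background-subtracted by Agilent Feature Extraction. The version is 9.5.3.1 per the file headers and 10.5.1.1 per the submitters' processing notes, and this difference was not resolved. The deposited mean intensity and local background intensity of each spot served an alternative. A value table of the authors also gives a linear intensity per spot: it lay within 1% of the processed intensity for 100% of the spots it lists on each array, with medians of 4.77, 10.8 and 28.2 for replicates 1, 2 and 3, so it is uncentred and is no independent alternative.

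Each array has 39102 spots, of which 1417 are controls and were left out, and 37685 are gene spots for 37478 probes. Spots of one probe were averaged. Outlier-flagged gene spots (20, 10 and 6 on replicates 1, 2 and 3) did not count as detected, and 0 probes were saturated. Main levels are log2 of the processed intensity minus the log2 of the array's 75th percentile over all gene probes. A probe was called detected where the deposited well-above-background flag was set, and a gene where a probe of it was flagged on all 3 arrays. Of 153 negative control spots, 0, 3 and 1 carried that flag. The lowest signal well above background was 7.38, 6.94 and 12.3, and probes well above background made up 39.5%, 54.0% and 56.8%, so replicate 1 sets most limits of detection. Arrays give no counts, so their number limits the precision.

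Probes were assigned to genes through the locus codes in the array files: 25665 genes had a probe, of which 25449 matched the locus tags of the reference table (assembly TAIR10.1, used for names only). The level of a gene is that of its probe flagged on the most arrays, then of the highest mean signal. Of 541 genes with several probes, 237 had probes that disagreed on detection on all 3 arrays, and 234 probes list several loci. The 5 organelle genes with a probe were kept out of the background, and 3 of them were detected. Probe coordinates are printed as the files give them, and the genome build behind them is not given in the sources used here.

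The tests of detection, agreement and the array set apart, the 21 lists, the naming rule and most alternatives were fixed before the data were examined. The share of each of 21 lists (368 distinct genes) and 22 families detected on all 3 arrays was compared with all other nuclear genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment at 0.05 within each set of tests. Genes are not independent replicates, so these p-values describe the genes of these arrays. Families were picked by words in the array descriptions. From the lists, 1 member was dropped because the reference gives its symbol to another locus. The array of the second slide was compared with the other 2 by limma (lmFit and eBayes with a trend) over the 23513 probes well above background on at least 1 array. This assumes that the lone array varies like the others, which 3 arrays cannot test. Where the dimmer side was not well above background on any of its arrays, as for 58 of the 451 genes called, the fold is a lower bound. It was taken against the higher of the probe's own level and the lowest level well above background on each dim array. The median difference of a list was placed among 10000 random lists matched on level. Medians were also taken with each value not well above background raised to the lowest level well above background on its array. The random lists, this floor and the adjustment over a list alone were not part of the plan.

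Genes were named from among the 115 members marked in advance in the lists, of which 78 were detected and 14 passed on no array, up to 3 further detected members of each list with the smallest SD, and the 20 genes with the highest mean unscaled processed signal. Not every gene that could be named is, and the choice among them was made with their values known. The text also names the 5 genes most above and the 5 most below on the array set apart, and the detected members of lists chosen as negative. Any other gene is said to be chosen after its values were seen.

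Alternatives for detection were the negative control spots (mean plus 3 SD), the positive-and-significant flag, a floor of 4 times the lowest signal well above background, 2 arrays instead of 3, 1 probe per gene, all probes detected, and leaving out each replicate. For levels and comparisons they were normexp background correction (offset 50) with quantile normalization, quantile normalization, the value table, no filter, a filter on all 3 arrays, each other array set apart, eBayes without a trend, and leaving out each replicate. Levels were also averaged over the probes of a gene. Cyclic loess and a 75th percentile over the 14177 probes detected on all arrays were added after seeing the data.

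The steps were tested on simulated data. For list detection, with 20 genes per list among 25660, 98 of 100 lists made with 90% detected and 99 of 100 made with 10% detected were called in the right direction, and 98 of 100 random lists were not called. For the array set apart, 47 of 100 probes changed by 2 on the log2 scale and 82 of 100 changed by 4 were recovered among 23513, with 20 false calls. For the random lists, 98 of 100 lists of 12 genes shifted by 1 and 5 of 100 unshifted lists fell outside the central 95%, among 19168 genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. Probes named by a chromosome position (8812) or by a transcript without a locus code (2430) entered the normalization and the tests between arrays but no gene count.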

Results

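Gene expression was profiled in stigmatic papilla cells of Arabidopsis thaliana, the elongated epidermal cells at the tip of the pistil that receive pollen. The cells were cut by laser from embedded stage 12 buds of the accession C24. RNA from 3 independent experiments was labelled with Cy3 and hybridised to 3 arrays, which made up 1 group. With no second tissue or treatment, the arrays answer which genes were measurable in papilla cells, how closely the experiments matched, and which genes set 1 array apart. Replicates 1 and 2 lay on the first slide and replicate 3 on the second, in a separate scan session. The 75th percentile of the processed signal was 31.6, 143 and 531 on replicates 1, 2 and 3. The spike-in transcripts did not follow it: their median log2 signal differed from replicate 1 by 1.56 on replicate 2 and by −1.54 on replicate 3, where 9 of 10 were dimmer. The signal of the sample relative to the spikes was thus far higher on replicate 3, and its effect on the comparisons below was not tested. Of 37478 probes, 14805, 20224 and 21290 were well above background on these arrays. The number of arrays limits the precision of every level given here.

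Of 25660 nuclear genes with a probe, 13342 (52.0%) were well above background on all 3 arrays and are called detected. A further 3188 genes passed on 2 arrays and 2638 on 1 array, while 6492 (25.3%) passed on none. Of 21 gene lists, 3 were detected more often than other genes, 4 less often, and 14 did not pass the test (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the 21 lists). Levels are log2 processed signals relative to the array's 75th percentile, as mean ± SD over the 3 arrays. They depend on the probe, so no gene's level is set against another's.

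Several genes known from the stigma were measured on every array. SLR1, an S-locus related glycoprotein gene, had a level of 10.18 ± 0.87 (SD, n = 3), and E6L1, a cell wall protein gene that acts in early pollen contact, one of 10.09 ± 0.90 (SD, n = 3). The receptor kinase genes FER and ANJ, which control pollen hydration, had levels of 5.07 ± 0.42 and 3.5 ± 0.09 (SD, n = 3). RALF33, which encodes a peptide ligand of these kinases, stood at 5.64 ± 0.05, the NADPH oxidase gene RBOHD at 6.28 ± 0.28 and the co-receptor gene LLG1 at 2.59 ± 0.22 (SD, n = 3). The acyltransferase gene GLC was at 9.21 ± 0.29 and EXO70A1, an exocyst gene needed for pollen acceptance, at 1.33 ± 0.20 (SD, n = 3). ARK1, an S-domain receptor kinase gene, was not well above background on any array. Of the 19 stigma and pollen acceptance genes 14 were detected (73.7% against 52.0% of other genes), which did not pass the test (adjusted p = 0.157, Fisher's exact test). With a stricter signal floor, 4 times the lowest signal, 13 of the 19 were detected and the list passed (adjusted p = 0.0228, Fisher's exact test). It did not pass in any other detection alternative. The probe for SLR1 lies on chromosome 3 from 3818320 to 3818379 and that for E6L1 on chromosome 2 from 14328273 to 14328332, as the array files give them without naming a build.

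**Figure D1:**
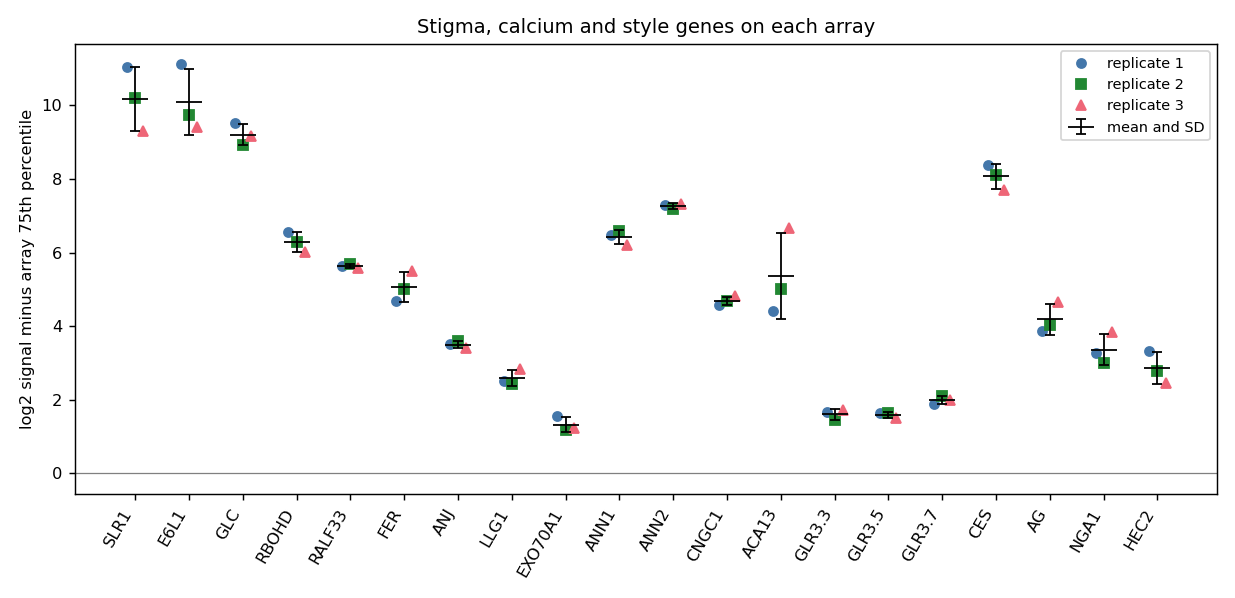
Levels of 20 stigma, calcium and style genes on each array, as log2 processed signal minus the array's 75th percentile (y axis), with symbols for replicates 1, 2 and 3 and a bar for the mean and SD. The replicates lay close for RALF33 (SD 0.05) and apart for ACA13 (SD 1.18), and levels of different genes are not comparable because their probes differ.

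Calcium transport genes included a pump gene that differed between the arrays. ACA13, which encodes a plasma membrane calcium pump of papilla cells, had levels of 4.41, 5.0 and 6.68 on replicates 1, 2 and 3. The glutamate receptor-like channel genes GLR3.3, GLR3.5 and GLR3.7 had levels of 1.61 ± 0.15, 1.60 ± 0.08 and 2.00 ± 0.12 (SD, n = 3). The annexin genes ANN1 and ANN2, whose products bind calcium and membranes, stood at 6.42 ± 0.20 and 7.27 ± 0.08 (SD, n = 3). The cyclic nucleotide-gated channel genes CNGC1 and CNGC2 were at 4.69 ± 0.12 and 0.69 ± 0.43, and the stretch-activated channel gene MCA1 at 1.88 ± 0.23 (SD, n = 3). Detected members numbered 7 of 20 glutamate receptor-like channels (adjusted p = 0.288), 10 of 20 cyclic nucleotide-gated channels (adjusted p = 1), 14 of 20 calcium pumps and exchangers (adjusted p = 0.246) and 6 of 9 annexins and other calcium channels (adjusted p = 0.596), all by Fisher's exact test. None of these 4 lists passed the threshold.

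Regulators of style and stigma growth were present alongside organ identity genes. CES, a basic helix-loop-helix factor gene of the brassinosteroid response, stood at 8.07 ± 0.34, and its relative BEE1 at 5.93 ± 0.26 (SD, n = 3). AG, the carpel and stamen identity gene, was at 4.19 ± 0.43, the style factor genes NGA1 and NGA2 at 3.37 ± 0.43 and 2.5 ± 0.28, and HEC2 at 2.86 ± 0.43 (SD, n = 3). STY1 was not well above background on any array, CRC was so on 1 array and SPT on 2. Of the 18 carpel, style and stigma regulators 12 were detected (adjusted p = 0.342, Fisher's exact test). Among genes of petals, stamens and the perianth, 6 of 9 were detected (adjusted p = 0.596, Fisher's exact test), with SEP1, SEP2 and SEP3 at 4.39 ± 0.21, 4.47 ± 0.26 and 3.37 ± 0.30 (SD, n = 3). The petal and stamen genes AP3 and PI passed on 2 arrays and AP1 on 1.

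The cuticle list was detected more often than other genes, at 25 of 29 members (86.2%, adjusted p = 0.000732, Fisher's exact test). The wax transporter gene CER5 had a level of 4.18 ± 0.17, the wax synthesis gene CER3 one of 3.98 ± 0.33 and the very long chain fatty acid gene CER6 one of 2.14 ± 0.14 (SD, n = 3). The cutin genes GPAT6, CYP86A4 and CYP77A6 were at 4.86 ± 0.59, 3.97 ± 0.34 and 3.5 ± 0.15 (SD, n = 3). Of the cuticle regulators, SHN1 and SHN2 passed on no array and SHN3 on 1. Epidermis identity genes did not pass the test at 8 of 13 detected (adjusted p = 0.647, Fisher's exact test), with the epidermal factor genes ATML1 at 2.12 ± 0.49 and PDF2 at 1.07 ± 0.49 (SD, n = 3). The exocyst list, which holds the subunits of a secretory tethering complex, had 12 of 17 detected (adjusted p = 0.260), with SEC8 at 2.86 ± 0.08 and SEC6 at 2.09 ± 0.17 (SD, n = 3). It passed when only 2 arrays were required, at 16 of 17 (adjusted p = 0.0282, Fisher's exact test). Aquaporins, which are water channels, had 15 of 23 detected (adjusted p = 0.327, Fisher's exact test), with PIP1;2 at 4.67 ± 0.82 and PIP2;7 at 4.57 ± 1.04 (SD, n = 3).

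All 15 housekeeping genes were detected (adjusted p = 0.000620, Fisher's exact test), with ACT2, UBQ10 and PP2AA3 at 5.43 ± 0.37, 6.20 ± 0.31 and 1.09 ± 0.08 (SD, n = 3). Photosynthesis genes were detected more often than other genes, at 41 of 47 (87.2%, adjusted p = 9.98e-06, Fisher's exact test). The light-harvesting genes LHCA1 and LHCB5 stood at 5.97 ± 0.22 and 4.91 ± 0.12, the Rubisco small subunit gene RBCS1A at 6.05 ± 0.39 and the Rubisco activase gene RCA at 3.56 ± 0.25 (SD, n = 3).

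**Figure D2:**
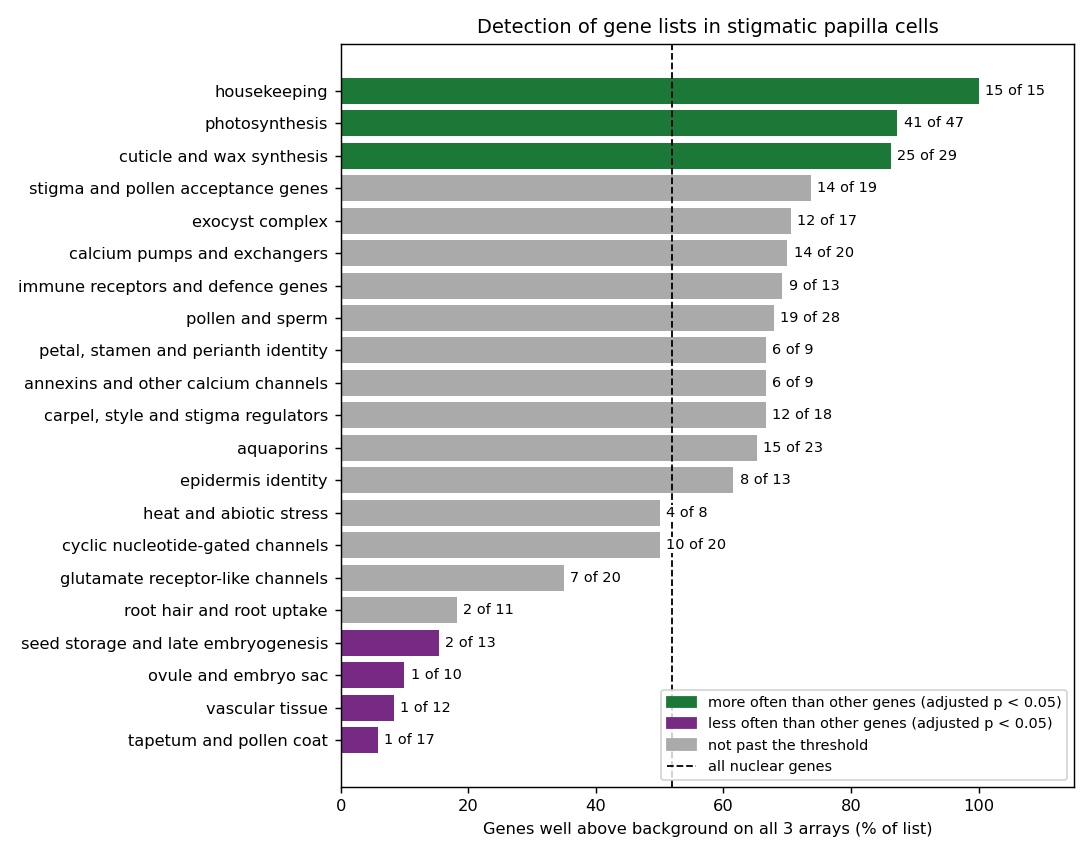
Share of each of the 21 gene lists that was well above background on all 3 arrays (x axis, percent), with the number of members beside each bar and a dashed line at the 52.0% of all nuclear genes. Green bars passed the test above other genes, purple bars below, and grey bars did not pass, and the tapetum list was lowest at 1 of 17.

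Markers of other cell types gave a mixed result. Tapetum and pollen coat genes were detected less often than other genes, at 1 of 17 (adjusted p = 0.000620, Fisher's exact test), the member being LAP6, a sporopollenin synthesis gene, at −1.70 ± 0.57 (SD, n = 3). Vascular genes (1 of 12, adjusted p = 0.0104), ovule and embryo sac genes (1 of 10, adjusted p = 0.0309) and seed genes (2 of 13, adjusted p = 0.0309) were also detected less often by Fisher's exact test. The detected members were the sucrose transporter gene SUC2 (2.63 ± 0.95), the ovule identity gene STK (−0.15 ± 2.44) and the late embryogenesis genes EM1 (−3.24 ± 1.63) and EM6 (−3.48 ± 1.58; SD, n = 3). When only 2 arrays were required, 5 of 12 vascular genes (adjusted p = 0.228) and 5 of 10 ovule genes (adjusted p = 0.478) were detected, and neither list passed Fisher's exact test. Root genes did not pass the test at 2 of 11 (adjusted p = 0.0853, Fisher's exact test), with the iron transporter gene IRT1 at −1.02 ± 0.54 and the radial patterning gene SCR at 2.49 ± 0.18 (SD, n = 3).

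Pollen and sperm genes did not pass the test: 19 of 28 were detected (67.9%, adjusted p = 0.246, Fisher's exact test). The pollen tube pectin methylesterase genes VGD1 and PPME1 stood at 4.41 ± 0.60 and 2.86 ± 0.52, the pollen actin factor gene ADF7 at 1.11 ± 0.26, and the male germline histone gene MGH3 at −1.51 ± 0.36 (SD, n = 3). These genes differed together between arrays: replicate 2 minus replicate 1 had a median of −0.72 over the 26 measured members and was above 0 for 2 of them, against −0.28 to 0.20 for the central 95% of random lists matched on level. No such median is given for the 9 measured ovule genes. BEL1, and EC1.2 and EC1.5, both named after their values were seen, passed on replicate 2 alone. They entered through that array, which favours a higher median there. Only STK among the 9 was well above background on all 3 arrays. It was at 2.5 on replicate 2 and at −0.65 and −2.31 on replicates 1 and 3.

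Defence genes were detected at 9 of 13 (adjusted p = 0.357) and heat and stress genes at 4 of 8 (adjusted p = 1), neither past Fisher's exact test. The flagellin receptor gene FLS2 passed on 1 array only, while EFR, the receptor gene for elongation factor Tu, was at 2.61 ± 0.10 and the kinase gene BIK1 at 3.99 ± 0.25 (SD, n = 3). The defensin gene PDF1.2 passed on no array. ZAT12, a stress-induced zinc finger gene, was at 4.76 ± 0.38, and the heat shock genes HSP70 and HSP101 at 1.13 ± 0.17 and −1.50 ± 0.45 (SD, n = 3).

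The 20 genes with the highest mean processed signal are named here without order, and which genes these are depends on their probes. The mean is over unscaled signals, so replicate 3, the brightest array, weighs most in this choice. Among them were SLR1, E6L1, GLC and CES, the lipoxygenase gene LOX1 (9.64 ± 0.48), the acyltransferase gene GPAT1 (8.20 ± 0.34), the expansin gene EXPA6 (8.27 ± 0.07) and the lipid transfer protein gene LP1 (8.47 ± 0.24; SD, n = 3). The putative peroxidase genes AT4G11290 and AT5G19880 were at 9.48 ± 0.37 and 8.99 ± 0.31, the dirigent protein gene DIR6 at 8.95 ± 0.27, the blue copper protein gene BCB at 8.91 ± 0.33 and the fatty alcohol oxidase gene FAO3 at 7.71 ± 0.29 (SD, n = 3). The isoprenoid gene IPP1 (8.07 ± 0.10) and the polyubiquitin gene UBQ11 (8.05 ± 0.22) were also among them. The others were AT1G48750 (8.60 ± 0.24), AT2G41800 (9.24 ± 0.15), AT4G22240 (8.13 ± 0.18), AT5G44020 (7.90 ± 0.36) and AT3G15450, whose level was 4.57, 5.83 and 8.96 on replicates 1, 2 and 3.

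Of 22 gene families picked by their array descriptions, 3 were detected more often than other genes, 15 less often and 4 did not pass Fisher's exact test. Proteasome subunits (59 of 62, adjusted p = 3.8e-13), ribosomal proteins (304 of 365, adjusted p = 2.41e-35) and chaperones (182 of 257, adjusted p = 2.41e-09) were detected more often. Families detected less often included F-box proteins (190 of 734, adjusted p = 7.88e-47), NBS-LRR disease resistance proteins (37 of 221, adjusted p = 7.92e-27), cytochromes P450 (58 of 247, adjusted p = 2.99e-19), MADS-box factors (18.8% detected, adjusted p = 2.79e-11) and WRKY factors (18 of 74, adjusted p = 3.89e-06). Protein kinases, at 538 of 1076, did not pass (adjusted p = 0.221, Fisher's exact test). Pentatricopeptide repeat proteins, which act on organelle RNA, were detected less often (190 of 455, adjusted p = 2.11e-05), a direction that turned around when 2 arrays sufficed, at 8.70 percentage points above other genes.

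The experiments matched more closely for bright probes. Over the 14177 probes well above background on all 3 arrays, the median SD of the log2 level was 0.300 and 93.3% of the probes had an SD under 1. Among them, 92.2% lay within 2-fold between replicates 1 and 2, 82.7% between 1 and 3 and 88.4% between 2 and 3. Over the 23513 probes that passed on at least 1 array, the median SD was 0.448 and Pearson's r was 0.927 between replicates 1 and 2, 0.893 between 1 and 3 and 0.893 between 2 and 3. These correlations are across probes, which are not independent replicates.

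Replicate 3, the only array of the second slide, was set against the mean of the other arrays. A lone array has no replicate, so every call below rests on the assumption that it varies like the others and on the trend of variance with signal that limma fits. In the simulation of this comparison, false calls made up a larger share than the 0.05 aimed at. Without that trend, or after quantile normalization, limma called 0 probes (2675 and 2231 at an unadjusted p under 0.05), and after normexp correction and quantile normalization it called 15 higher and 9 lower. With the trend and the main scaling, MAH1, which encodes a wax alkane hydroxylase, fell by 7.86 there on the log2 scale (adjusted p = 2.22e-05, limma). The germin-like gene GER3 fell by 7.39 (adjusted p = 3.91e-05) and AT1G09310 by 6.97 (adjusted p = 2.22e-05). The sesquiterpene synthase gene TPS21 was not well above background on replicate 3 and was at least 86.1-fold lower there (adjusted p = 0.000377), and PRE1, a growth-promoting helix-loop-helix gene, at least 32.7-fold lower (adjusted p = 0.00379). GAT1_2.1, a glutamine amidotransferase-like gene, was higher by 6.67 (adjusted p = 4.91e-05), the phosphodiesterase gene GDPD2 by 6.15 (adjusted p = 6.3e-05), the dark-induced gene SEN1 by 5.80 (adjusted p = 0.00312) and the gibberellin-regulated gene GASA1 by 5.20 (adjusted p = 0.00747). BT1, which encodes a BTB and TAZ domain protein, was at least 51.3-fold higher (adjusted p = 0.0041). GAT1_2.1, SEN1 and GASA1 were well above background on only 1 of the other 2 arrays, replicate 2, so their differences depend on a level below background on replicate 1. In all, 235 probes were higher and 247 lower on replicate 3 among 23513 tested with limma's moderated test, or 222 and 229 of 19168 genes. With replicate 1 or replicate 2 set apart instead, limma called 0 probes (812 and 282 at an unadjusted p under 0.05), and slide and experiment cannot be told apart for replicate 3.

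Several lists fixed in advance held genes past the threshold on replicate 3 in limma's fit with the trend, and 0 of these calls were kept without it. Of 11 measured defence genes, 4 fell and 1 rose (5 also when adjusted over the list alone): the storage protein genes VSP1 (by 5.81) and VSP2 (by 5.03), THI2.1, a thionin gene (by 4.41) and LOX2, a jasmonate synthesis gene (by 3.39), fell, and PR5, a pathogenesis-related gene, rose by 1.58. Of 27 cuticle genes, 6 fell and 0 rose (8 changed when adjusted over the list alone), among them CER4, which makes primary alcohols (by 3.00), LTPG1, a lipid transfer gene (by 2.75), and CER1, which makes alkanes (by 2.1). The list's median was −0.16, inside the central 95% of random lists matched on level (−0.20 to 0.29). Under the other scalings, for which no random range was drawn, it was −0.29 to −0.23. Replicate 1 stood further apart for this list, with a median of 0.44 when it was set apart instead. The same held for the defence list, with 0.56 for replicate 1 and −0.09 for replicate 3. With values not well above background raised, the defence median on replicate 3 was −0.66 (random range −0.45 to 0.33), so the −0.09 depends on such values. Of 18 aquaporins, PIP1;2 and PIP2;7 rose by 1.41 and 1.78 and the tonoplast genes TIP1;1 and TIP2;1 fell by 2.31 and 2.01, the last chosen after its values were seen. When adjusted over the list alone, 12 aquaporins changed, and the list's median of 1.1 lay outside the random range of −0.31 to 0.30, with 0.60 to 1.03 under the other scalings.

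Of 47 photosynthesis genes 3 fell (9 changed when adjusted over the list alone), namely RBCS1B, RBCS2B and RBCS3B, near-identical Rubisco small subunit genes named after their values were seen, by 2.59, 1.56 and 1.96. The median of that list went the other way at 0.38 (random range −0.14 to 0.23), with 36 of 47 members higher, and was −0.29 with replicate 1 set apart and −0.09 with replicate 2. Of 9 petal and stamen genes 2 changed (2 when adjusted over the list alone): PI, not well above background on replicate 1, rose by 3.24 and FUL, a fruit identity gene named after its values were seen, fell by 6.46. Calcium pumps, style regulators and vascular genes had 1 change each (1 each when adjusted over the list alone), with ACA13 higher by 1.97 (adjusted p = 0.0169), STY2, named after its value was seen, by 1.73 (adjusted p = 0.0351) and SUC2 by 1.58 (adjusted p = 0.0239). Medians lay just outside the random ranges for calcium pumps at 0.37 (−0.33 to 0.30), style regulators at 0.46 (−0.39 to 0.33) and cyclic nucleotide-gated channels, which had 0 calls, at 0.35 (−0.56 to 0.29). With values not well above background raised to the lowest level that was, they were 0.32, 0.29 and 0.35. The random ranges of the raised values were −0.35 to 0.26, −0.45 to 0.26 and −0.71 to 0.14, so these medians also lay outside. Replicate 1 also stood apart for calcium pumps, with a median of −0.39 when it was set apart instead, and for the channels, with 0.55. The median of the channels on replicate 3 was 0.16 after normexp correction and quantile normalization. No median on replicate 3 is given for vascular and ovule genes, since only 1 of 8 and 1 of 9 measured members were well above background on all 3 arrays. Of the ovule genes 0 passed (2 when adjusted over the list alone). The stigma and pollen acceptance list had a median of −0.04, with 8 of 17 measured members higher. Its members differed both ways, by amounts that did not pass limma's threshold. SLR1 was lower by 1.33 and E6L1 by 1.01, and ROP2, named after its value was seen, was higher by 1.22. The pollen list of 26 measured members had a median of 0.46 (random range −0.35 to 0.23), with 23 of them higher. This came from replicate 2: the median was 0.72 for replicate 3 minus replicate 2 and 0.02 for replicate 3 minus replicate 1, with 13 members higher.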

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

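The test of base composition was chosen after the counts of these probes were seen, and what it would show was written down before it was run. Probes outside the gene counts gave signal. Of 8812 probes named only by a chromosome position, 330 (3.74%) were well above background on all 3 arrays, and of 2430 probes named by a transcript or expressed sequence tag without a locus code, 329 (13.5%) were. Among the 153 negative control spots, 0, 3 and 1 carried the flag on replicates 1, 2 and 3, and among probes of genes 51.5% passed on all 3 arrays.

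The position probes were set against base composition. Non-specific hybridisation that follows base composition may account for part of the signal: 7.26% of the probes in the highest of 4 equal groups by GC content passed against 1.72% in the lowest, a ratio of 4.21. For gene probes the shares were 54.7% and 48.9%. Unlisted transcripts would also tend to be richer in GC than sequence between genes, so this test leaves both open, and no biological explanation was tested.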

How the results depend on the processing

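Cyclic loess and the common percentile (the 75th percentile over probes detected on all arrays) were the alternatives chosen after seeing the data. The count of detected genes stayed between 9235 (signal floor of 4 times the lowest signal) and 18122 (positive and significant flag) against 13342, and the housekeeping, photosynthesis, cuticle, tapetum and seed lists kept their direction and side of the threshold in all 9 detection alternatives. Differences below are percentage points of list minus other genes. With the floor of 4 times the lowest signal, the stigma and pollen acceptance genes passed (32.5) while vascular tissue (−27.7) and ovule genes (−36.0) did not, and 2 lists instead of 4 were detected less often. With at least 2 arrays, the exocyst complex (29.7) and root genes (−46.3) passed, vascular tissue (−22.8) and ovule genes (−14.4) did not, and pentatricopeptide repeat proteins turned to 8.70. With the positive and significant flag, pollen and sperm genes passed (25.8), ovule genes did not (−30.6), and pentatricopeptide repeat proteins turned to 10.4. With negative control spots, root genes passed (−38.1) and ovule genes did not (−26.3). Root genes also passed with 1 probe per gene (−42.6) and with all probes detected (−42.0). Leaving out a replicate moved the exocyst complex between 17.9 and 30.7, vascular tissue between −44.3 and −21.8, ovule genes between −42.7 and −13.5, root genes between −45.3 and −34.1 and pentatricopeptide repeat proteins between −10.9 and 9.46. The value without replicate 1, the dimmest array, was 30.7, −21.8, −13.5, −45.3 and 9.46 for these, and changed each call. The cause was not tested beyond this. The mean correlation between arrays was 0.904, and 0.961 with normexp and quantile normalization, 0.927 without a filter, 0.931 for probes well above background on all 3 arrays and 0.893 to 0.927 leaving out a replicate. The median SD was 0.448, and 0.193, 0.992, 0.300 and 0.308 to 0.418 under the same settings. The offset of normexp compresses low levels by construction. For the array of the second slide (235 probes higher, 247 lower), normexp and quantile normalization gave 15 and 9, quantile normalization 0 and 0, cyclic loess 413 and 418, the common percentile 274 and 432, no filter 593 and 680, and eBayes without trend 0 and 0, with limma throughout. At an unadjusted p under 0.05 the settings with 0 calls had 2231 (quantile) and 2675 (without trend) probes, and setting replicate 1 apart (0 and 0) or replicate 2 apart (0 and 0) gave 812 and 282. All 24 calls of the normexp setting and 482 of the calls of cyclic loess were shared with the main ones, and the median difference of all tested probes ran from −0.18 (common percentile) to 0.07 (quantile), and was −0.66 without a filter. Leaving out a replicate leaves 1 array against 1, so no test of this comparison was run. No paired analysis was possible because the series has 1 group. Of the 173 named levels, 129 moved by over 1 SD with normexp and 166 with the common percentile, which shifts every level by about the same amount, 5 with the mean over probes and 0 with quantile normalization or the value table. Leaving out 1 of 3 values cannot move a mean by over 1 SD, so it tests no level. Signal over background, above all that of replicate 1, limits detection.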

Other observations

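In this part, the starvation, clock and abundant pollen lists were chosen after the brightest genes (AT3G15450 among them, which is in none) and before the differences of their members were seen, the jasmonate list was chosen after the defence genes were seen, and the comparison of the clock lists with replicate 1 alone, the starvation median without its top genes and the medians with raised values are the tests chosen only after the result was seen. Genes induced by darkness and sugar starvation were higher on replicate 3. All 12 lay above the mean of the other arrays, 8 past limma's threshold (11 when adjusted over the list alone), with a median of 3.23 on the log2 scale. ASN1, which encodes an asparagine synthetase induced in the dark, was higher by 3.37 (adjusted p = 0.00462), the raffinose synthase-like gene DIN10 by 4.40 (adjusted p = 0.000243), the xylosidase gene BXL1 by 4.88 (adjusted p = 0.000304) and the trehalose phosphate synthase-like gene TPS8 by 3.61 (adjusted p = 0.000437). GAT1_2.1 and SEN1, named above among the genes most different on replicate 3, belong to the list, and without them the median of the other 10 was 2.94 (random range −0.45 to 0.40). With values not well above background raised to the lowest level that was, the median of all 12 was 3.08. It stayed between 2.18 and 3.44 under the other scalings. It was also above 0 for replicate 2 minus replicate 1, at 0.59 over 12 genes, against −0.35 to 0.29 for the central 95% of random lists.

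The 4 defence genes that fell on replicate 3 included the jasmonate-responsive genes VSP1, VSP2 and LOX2. A list of 14 other jasmonate genes showed no common fall. Of these 12 were measured, with a median of 0.37 (random range −0.43 to 0.38), and 10 were higher on replicate 3. The 10 included the synthesis genes AOS (0.26) and OPR3 (0.48), named after their values were seen. The list's median therefore does not test whether responsive genes such as VSP1 fell together. It was −0.495 with replicate 2 set apart instead and 0.12 with replicate 1, so low values on replicate 2 carry much of the 0.37. Only the jasmonate-induced aminotransferase gene CORI3 (lower by a log2 difference of −2.90, adjusted p = 0.0266) and the chlorophyllase gene CLH1 (−2.08, adjusted p = 0.0101) passed limma's threshold, while the repressor gene JAZ10 differed by 0.52 and MYC2, the central regulator gene, by 0.20, neither past it. Ribosomal protein genes had a median of −0.33 on replicate 3, and 88 of 347 were higher, against −0.04 to 0.09 for random lists, with −0.43 to −0.29 under the other scalings. The list differed as much on replicate 1, where the median against the other arrays was 0.31. Leaving the random range was not particular to ribosomal proteins. Many other families did so on replicate 3, in both directions, such as chaperones at −0.18 (−0.11 to 0.07) and lipases at 0.13 (−0.28 to 0.02).

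For the genes that differ on replicate 3, a trend of the difference with signal level was tested with cyclic loess. All calls kept their direction and passed, which is what had been written down against a trend. Quantile normalization did not keep the calls, and their number follows the variance pooled in each fit, so calls cannot decide this. The starvation list's median was 3.23, and 3.38 with cyclic loess and 3.44 with quantile normalization, which argues against such a trend for that list. Darkness or sugar starvation of the buds may account for part of the pattern, as the starvation list's median of 3.23 lay outside the random range of −0.43 to 0.37. That list leaves out genes of other kinds that fell, and those given next were picked from this side after their values were seen. The topoisomerase gene TOPII was at least 22.7-fold lower on replicate 3, the cyclin gene CYCD3;1 at least 15.6-fold and the stomatal gene TMM at least 54.0-fold. No list of such genes was tested, so the tissue they came from stays open. Time of day at collection also stays open: the morning minus evening clock genes gave −0.88 against both other arrays, outside the range of random pairs (−0.58 to 0.77), which is what had been written down for it. Against replicate 1 alone the value was −0.35, inside the range (−0.62 to 0.94), and replicate 2 minus replicate 1 gave 1.24, so replicate 2 carries much of this difference and the test against replicate 1 decides nothing. Slide, scan session, the amount of sample relative to the spikes and experiment cannot be told apart for replicate 3.

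For the pollen genes measurable in the papilla samples, probes shared with paralogs stay open. The probes of 19 of 19 detected members list 1 locus, but only 231 genes on the array have a chosen probe that lists several, and the locus codes do not measure similarity of sequence, so this excludes nothing although it met the outcome written down against paralogs. Pollen or pollen RNA in the dissected material also stays open. Of 12 genes abundant in mature pollen 10 were well above background on all 3 arrays, with VGD1 at 4.41 and ADF10 at 1.58, but all 12 belong to the pollen list, so this count restates the pattern and does not separate pollen RNA from expression in papilla cells, which was not tested.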
